A study of Mus musculus with 6 samples.

How the data were processed

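Total RNA of pooled mouse oocytes was labelled with Cy3 and hybridised to mouse microRNA arrays annotated against miRBase 10.1, per the labels and the series text. Images were processed with Agilent Feature Extraction 9.5, per the submitters' processing notes. The deposited scanner files give, per the file headers, one total signal intensity per microRNA on a linear scale, an error of that signal, a call of detected or not detected, and the fraction of the microRNA's spots that were kept as inliers. These intensities had the background subtracted (between 42.3% and 56.0% of the microRNA entries on an array had a signal at or below 0) and were not normalized between arrays. The deposited series table repeats the same intensities with values under 10 set to 0: 0 of 577 entries differed on any array, and the median of each column was 0. It is thus linear and uncentred, and it set between 23 and 31 detected entries per array to 0. The files name no genome build, so no coordinates are given. The RefSeq table of assembly GRCm38.p6 was used only to see that Mir483 lies within the Igf2 gene.

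The 577 microRNA entries were used (567 of mouse and 10 of a mouse herpesvirus), and 23 control entries were left out. Each array's signals were divided by its 75th percentile over the 56 microRNAs detected on all 6 arrays, relative to the geometric mean of the arrays. Scaled signals were then floored at 6.17, the highest over arrays of the lowest detected scaled signal, and put on the log2 scale. The floor shrinks differences that involve floored values and, where both groups lie near it, can turn their sign. A microRNA was tested where both arrays of at least 1 compared group detected it. A mean per group was fitted to all 6 arrays, so that the groups share 1 estimate of the spread, with lmFit and eBayes of limma 3.58.1 in R 4.3.3, without trend. Tests were two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The design leaves 3 residual degrees of freedom. Of the 97 microRNAs fitted, 16 were at the floor on all 6 arrays, which pulled the prior SD to 0.00743 with 0.441 prior degrees of freedom; very small standard errors, such as that of miR-150*, should be read with that in mind. The number of arrays limits the precision. Means ± SD are of the scaled signal before the floor.

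Of 21 lists of microRNAs, the 8 with at least 3 tested members were tested with camera of limma at a preset correlation of 0.01, adjusted over the lists; an estimated correlation and fry were alternatives. Lists not described with the results are given in the closing section. Named microRNAs were chosen by a rule. It took, per comparison, the 12 largest rises and 12 largest falls past the threshold whose groups did not overlap, and up to 4 members of each list with the smallest unadjusted p. miR-197, let-7f, let-7g, miR-345-5p, miR-483*, miR-484 and miR-702 were named outside that rule, after their values were seen. Where no array of a group detected a microRNA, the change is given as a bound, or as the fitted fold where both are equal.

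The design, the lists, the rule for named microRNAs and these alternatives were fixed before the data were examined: 5 other ways to scale the arrays, a lower floor, a pseudocount of 1, no filter, detection on all 6 arrays, the series table, eBayes with a trend or robust, only the 4 arrays compared, the replicate number as a block, each array left out, thresholds of 0.01 and of 2-fold, and detection as 3 times the deposited error. Scaling by hur control entries, leaving out 6 entries that differed between the young large arrays, keeping only microRNAs above the floor, and a crossed block were added after the data were seen.

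The fit was tested on 100 simulated sets of 6 arrays per fold size and comparison, drawn from the young large signals with the real scaling factors and 20 changed microRNAs. For the ageing comparison, with about 106 microRNAs tested, 27.2% of 1.5-fold, 74.2% of 2-fold and 90.0% of 4-fold changes were recovered. False calls made up 8.26%, 9.45% and 29.7% of calls, and 3.66%, 3.50% and 4.13% with the scaling factors known. For growth 27.2%, 75.3% and 91.7% were recovered (106, 105 and 105 tested), with 13.2%, 13.1% and 31.2% false calls, or 9.35%, 7.30% and 8.19% with known factors. Most of the false calls at 4-fold were thus absent when the scaling factors were known. A let-7 list raised 2-fold was called by camera in 100 of 100 sets in each comparison. With no change it was called in 3 sets for ageing and 1 for growth, beside 6 and 5 calls of other lists. Simulated noise was independent between microRNAs, while the estimated correlation of let-7 members in the data was 0.90. The simulation therefore cannot vouch for the let-7 calls in the data. Figures were drawn with matplotlib 3.10.9.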

Results

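MicroRNA abundance was measured in oocytes of C57BL/6 mice with 6 one-colour Agilent arrays, each of which carried 577 microRNA entries from miRBase release 10.1. The arrays fell into 3 groups of 2. Young large oocytes came from mice aged 6 to 8 weeks and measured 60 to 80 µm across. Aged large oocytes had the same diameter and came from mice aged 41 to 43 weeks by most labels, although the sample descriptions give 42 to 44 weeks. Young small oocytes came from the younger mice and measured 20 to 50 µm; the titles call them non-growing and another label places them in primordial follicles. The series text says that each sample was run in duplicate, and no label names separate animals or pools, so p-values here measure only the spread between arrays, which may be technical.

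Oocytes carried a restricted set of microRNAs. Of the 577 entries, 108 were called detected on at least 1 array and 56 on all 6. Young large oocytes had 99.5 ± 3.54 detected microRNAs per array (SD, n = 2), aged large oocytes 84 ± 7.07 (SD, n = 2) and young small oocytes 58.5 ± 2.12 (SD, n = 2). The arrays also differed in brightness: the factor that put them on 1 scale was 1.94 and 1.48 for young large, 0.954 and 1.06 for aged large, and 0.582 and 0.589 for young small oocytes. A microRNA at the detection limit was therefore easiest to detect in young large oocytes. Both young large arrays detected 33 microRNAs that neither young small array did, and the reverse was seen for 0. A single entry, miR-720, later traced to a transfer RNA fragment, took between 88.5% and 91.0% of the detected signal on each array. Duplicate arrays correlated across microRNAs with r = 0.977 in young large, 0.992 in aged large and 0.996 in young small oocytes (log2 signal of microRNAs detected on both arrays, which are not independent replicates).

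Markers of other cell types were mostly undetected. Of 7 granulosa cell markers, miR-21 and miR-212 were detected. None of 5 stroma and smooth muscle markers (miR-143 and miR-145 among them), 2 arms of the endothelial miR-126 and 13 markers of liver, muscle, brain and pancreas was detected on any array. Of 7 blood cell markers, miR-223 was detected, and the highest raw signal of the other 6 on any array was 2.24. The miR-34 and miR-449 families were undetected in all 7 entries. One of 10 mouse herpesvirus entries, mghv-miR-M1-2, was called detected on all 6 arrays. Its raw signal was 25.01 and 54.3 on the young large arrays, 26.0 and 32.0 on the aged large arrays, and 26.7 and 25.6 on the young small arrays. It was 1 of 6 entries whose scaled signal was at least 2-fold lower on young large array 1 than on array 2. Among microRNAs detected on both arrays of a group, none differed by 2-fold between duplicates in the other groups.

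**Figure D1:**
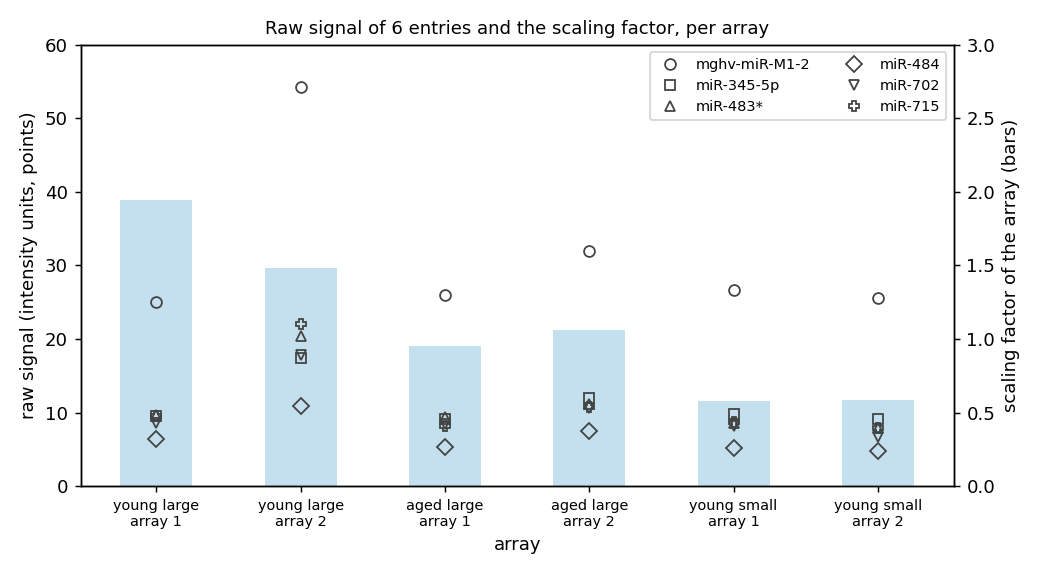
Raw signal in intensity units (open symbols, left axis) of the 6 entries that differed at least 2-fold between the young large arrays after scaling, and the scaling factor of each array (bars, right axis). The viral entry mghv-miR-M1-2 lies between 25.01 and 32.0 on 5 arrays and at 54.3 on young large array 2, while the scaling factor falls from 1.94 to 0.582.

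The first comparison set aged against young large oocytes, the contrast the series text ties to reproductive ageing. miR-483, which lies within the Igf2 gene, rose the most: its scaled signal was 8.95 ± 0.0991 in young large and 124 ± 21.3 in aged large oocytes (SD, n = 2 each), a log2 change of 3.78 ± 0.13 (SE; limma, adjusted p = 0.000669). The other arm, miR-483*, had 0.15 ± 0.45 (SE) and did not pass, with 1 young large array under the floor. The rise is thus shown for miR-483 alone and not for its locus. let-7c and let-7b rose by 1.29 ± 0.08 and 1.26 ± 0.07 on the log2 scale (SE; limma, adjusted p = 0.00237 and 0.00186). miR-223, known from myeloid cells, rose by 1.11 ± 0.17 (SE; limma, adjusted p = 0.0233). miR-141 of the epithelial miR-200 family, miR-96 and miR-193 fell, with log2 changes of -0.81 ± 0.03, -0.80 ± 0.02 and -0.77 ± 0.02 (SE). For miR-193, 1 aged large array was under the floor, which narrows its standard error.

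Of 97 microRNAs tested, 29 passed the 0.05 threshold after adjustment, 14 higher and 15 lower in aged oocytes, and 41 had an unadjusted p under 0.05. A change of at least 2-fold was seen in 5 of them, each higher in aged oocytes: miR-483, let-7c, let-7b, miR-223 and miR-290-5p. The last had a log2 change of 1.20 ± 0.11 (SE) against young large signals that were detected but lay under the floor of 6.17. In all 29 the 2 groups did not overlap; chance gives that in 33.3% of microRNAs with 2 arrays against 2, and 60.8% of those tested showed it. Smaller rises were fitted for miR-320 (0.78), miR-671-5p (0.60), miR-709 (0.59), miR-342-3p (0.52) and miR-150* (0.47 on the log2 scale). Beyond those in the lists below, falls were fitted for miR-140* (-0.38) and miR-26a (-0.36).

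The let-7 family, which accumulates as cells differentiate, rose in aged oocytes. Of its 7 tested members 5 rose and none fell, also when adjusted over the list alone. let-7d, let-7a and let-7i had log2 changes of 0.60 ± 0.08, 0.59 ± 0.10 and 0.39 ± 0.06 (SE). let-7g and let-7f had 0.18 ± 0.07 and 0.19 ± 0.09 (SE) and did not pass. The median over the list was 0.59, positive under 6 of 7 scalings and -0.17 without any scaling. It was the 1 list of 8 tested that passed with camera (adjusted p = 0.00706), and it did not pass with an estimated correlation (adjusted p = 0.563 with an estimated correlation). The camera call held under 3 of 7 scalings and was lost without young large array 2 (adjusted p = 0.0795) and without young small array 1 (adjusted p = 0.0662), within a range of 1.64e-18 to 0.563 over all alternatives.

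Of 9 tested members of the miR-17-92 cluster and its paralogs, which are linked to proliferation, 4 fell, 1 rose and 4 did not pass, also when adjusted over the list alone. miR-19a, miR-19b, miR-20a and miR-20b had log2 changes of -0.62 ± 0.07, -0.55 ± 0.01, -0.40 ± 0.03 and -0.39 ± 0.06 (SE), and miR-92a had 0.19 ± 0.03 (SE). The list itself missed the threshold (camera, adjusted p = 0.0531; adjusted p = 0.563 with an estimated correlation). In the miR-15 and miR-16 family 2 of 3 tested members fell, miR-16 by a log2 change of -0.30 ± 0.01 and miR-15a by -0.25 ± 0.05 (SE; list by camera, adjusted p = 0.1). In the miR-30 family 2 of 5 fell, miR-30e with -0.44 ± 0.07 and miR-30a with -0.42 ± 0.07 (SE; list by camera, adjusted p = 0.195). All 3 families had negative medians under each of the 7 scalings. The other scalings moved the median log2 change of the tested microRNAs by between -0.76 and 0.055, which left little room for a positive sign.

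Of 7 tested arms of the miR-290 to miR-295 cluster, which is abundant in early embryos and embryonic stem cells, only miR-290-5p rose (list by camera, adjusted p = 0.329). In the miR-200 family, 1 of 2 tested members, miR-141, fell. Of 5 tested microRNAs linked to senescence, miR-22 fell (log2 change -0.37 ± 0.03, SE); miR-155, miR-29b and miR-21 had 0.21, -0.10 and -0.03 and did not pass (list by camera, adjusted p = 0.541). miR-21 and miR-212, the detected granulosa cell markers, had log2 differences of -0.03 ± 0.11 and 0.45 ± 0.38 (SE) and did not pass. miR-223, the detected blood cell marker, was 1 of the 5 that rose at least 2-fold. The viral entry had 0.40 and did not pass.

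The scaling set the balance of directions. Relative to the scaling used here, the median log2 change moved by -0.76 without scaling, -0.42 with the total signal, -0.39 with 4 control entries named hur and -0.17 with the percentile over all entries. The split was 3 higher to 55 lower without scaling, 4 to 24 with the total signal, 5 to 18 with hur entries, 8 to 17 with quantile normalization, 3 to 3 with the percentile over all entries and 16 to 12 with the median, beside 14 to 15. miR-483 and miR-193 passed in the same direction under all 7 scalings. Most of the other scalings moved changes down, which favours a fall such as that of miR-193. For miR-223 the log2 change was 0.35 to 1.16 and passed under 3 of 7, and it was not past the threshold when any 1 of the young large or aged large arrays was left out (limma, highest adjusted p = 0.109, without young large array 1; range over all alternatives 0.000207 to 0.226). miR-320 lost its call without any 1 of 5 arrays (limma, highest adjusted p = 0.175). Of 27 named microRNAs past the threshold, 11 kept the call whichever array was left out, miR-483, let-7b, let-7c, miR-141, miR-96 and miR-193 among them. The count of 29 fell to 16 without young small array 1 and to 19 without young small array 2 or young large array 1.

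**Figure D2:**
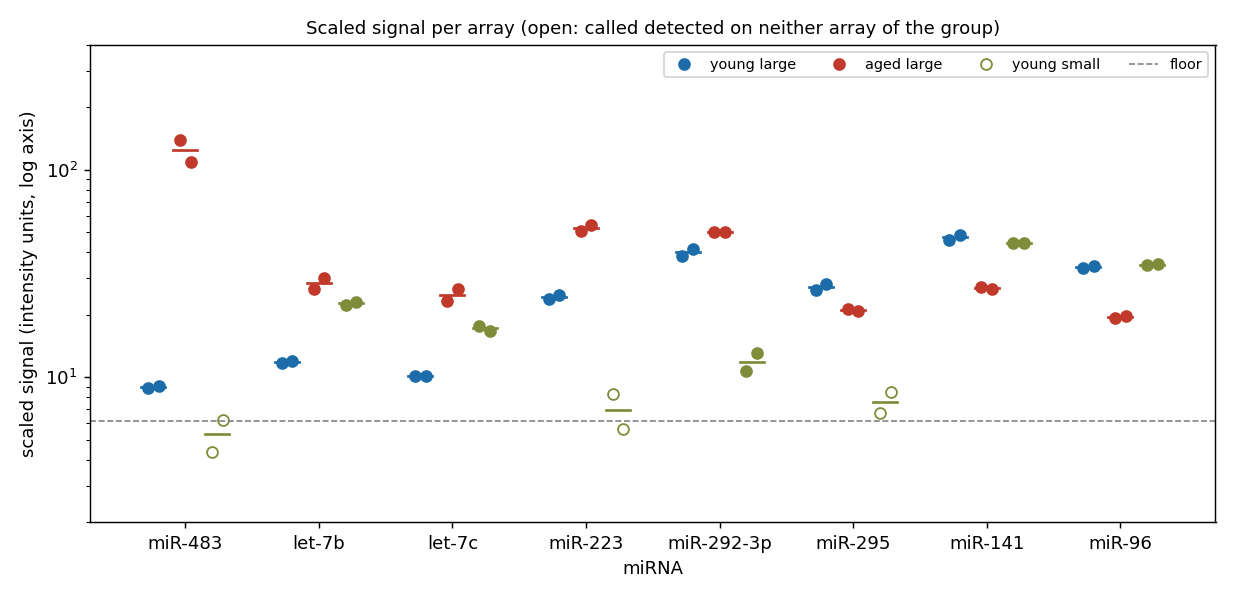
Scaled signal (intensity units, log axis) of 8 microRNAs on each of the 6 arrays; points are arrays, short lines the means of 2, open symbols mark groups in which neither array called the microRNA detected, and the dashed line is the floor of 6.17. miR-483 averages 124 in aged large and 8.95 in young large oocytes, and miR-295 averages 27.2 in young large oocytes and is undetected in young small ones.

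The second comparison set young large against young small oocytes, the contrast the series text ties to oocyte growth. The miR-290 to miR-295 cluster led the rises. miR-295 was at 27.2 ± 1.45 in large oocytes (SD, n = 2) and undetected in small ones, with a fitted 3.60-fold difference (limma, adjusted p = 0.004). miR-292-3p, miR-291a-3p and miR-294 rose by 1.75 ± 0.12, 1.55 ± 0.34 and 1.17 ± 0.10 on the log2 scale (SE). miR-223 was undetected in small oocytes, with 1 small array under the floor, and a fitted 3.40-fold higher in large ones (limma, adjusted p = 0.00569). let-7b, miR-877* and miR-291b-5p were lower in large oocytes, with log2 changes of -0.94 ± 0.07, -0.85 ± 0.12 and -0.85 ± 0.06 (SE). For miR-877* and miR-291b-5p the floor narrows these standard errors, as 1 young large array lay under it. Their raw signals were 0.47 and 0.32 log2 units higher in large oocytes. Signal that does not come from the labelled oocyte RNA was not tested for them.

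Of 94 microRNAs tested, 35 passed, 17 higher and 18 lower in large oocytes, and 43 had an unadjusted p under 0.05. A change of at least 2-fold was seen in 5, all higher in large oocytes: miR-295, miR-223, miR-292-3p, miR-291a-3p and miR-294. In none of the 35 did the groups overlap; chance gives that in 33.3% of microRNAs, and 64.9% of those tested showed it. Neither small array detected 7 of the 35. For miR-295, miR-223 and miR-342-3p (1.42-fold) the fitted fold is given, since the bound equals it. Bounds apply to the others: miR-193 was at least 1.77-fold, miR-140* at least 1.57-fold, miR-293 at least 1.55-fold and miR-197 at least 1.29-fold higher in large oocytes. Such a bound sets the mean of the large oocytes against, per array, the higher of the lowest detected signal and the microRNA's own. miR-652 rose by 0.95 ± 0.07 and miR-107 by 0.41 ± 0.04 on the log2 scale (SE). miR-709, miR-93, miR-29a, miR-26b and miR-29b had log2 changes of -0.75, -0.69, -0.59, -0.50 and -0.50.

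Of 7 tested arms of the miR-290 to miR-295 cluster, 5 rose and miR-291b-5p fell, also when adjusted over the list alone. miR-290-5p lay under the floor in both groups. The list median was 1.17 and was positive under all 7 scalings. The other scalings moved the median log2 change of the tested microRNAs by 0 to 1.53, which favours a positive sign. It passed with camera by a narrow margin (adjusted p = 0.0499), and did not pass with an estimated correlation (adjusted p = 0.435 with an estimated correlation). The call held under 3 of 7 scalings and was lost without either young large array or either aged large array (camera, adjusted p from 0.0659 to 0.0747; range over all alternatives 0.00201 to 0.435). miR-291b-5p and miR-877* were each under the floor on 1 of the 2 young large arrays. miR-291a-3p kept its call only when a young small array was the one left out (limma, highest adjusted p = 0.160, without young large array 2; range over all alternatives 0.001 to 0.393).

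The let-7 family was lower in large than in small oocytes. Of 7 tested members 6 fell, and all 7 did when adjusted over the list alone. let-7i, let-7c, let-7d and let-7a had log2 changes of -0.81 ± 0.06, -0.76 ± 0.08, -0.75 ± 0.08 and -0.53 ± 0.10 (SE). The list median was -0.75, negative under 6 of 7 scalings and 0.78 without any scaling. The list passed with camera (adjusted p = 0.00423) but not with an estimated correlation (adjusted p = 0.459 with an estimated correlation), nor without young large array 2 (camera, adjusted p = 0.0696). The call held under 6 of 7 scalings, and its adjusted p ranged from 3.25e-16 to 0.459 over all alternatives. In each of the 7 members both young large arrays lay below the other 4 arrays.

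In the miR-17-92 list 5 of 9 tested members fell, also when adjusted over the list alone. miR-20a, miR-92a and miR-19b had log2 changes of -0.51 ± 0.03, -0.38 ± 0.03 and -0.11 ± 0.01 (SE), and kept a negative sign under 6, 4 and 2 of 7 scalings. All 3 passed as higher without scaling, and miR-19b also with quantile normalization (0.29) and the series table (0.24). The list median was negative under only 3 of 7 (list by camera, adjusted p = 0.1). In the miR-30 family 3 of 5 rose, miR-30a by 0.41 ± 0.07, miR-30c by 0.37 ± 0.06 and miR-30e by 0.35 ± 0.07 on the log2 scale (SE; list by camera, adjusted p = 0.106), with a positive median under all 7 scalings. The other scalings favour that sign. In the miR-200 family miR-200c rose by 0.26 ± 0.05 (SE), and both tested members did when adjusted over the list alone. Of 5 tested senescence-linked microRNAs miR-29a and miR-29b fell (list by camera, adjusted p = 0.119). The granulosa cell markers miR-21 and miR-212 had log2 differences of -0.13 ± 0.11 and 0.40 ± 0.38 (SE) and did not pass, while miR-223 of the blood cell list was among the rises. The viral entry had -1.04 ± 0.58 (SE) and did not pass.

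Scaling moved this comparison as well. The median log2 change moved by 1.53 without scaling, 0.50 with the percentile over all entries, 0.42 with the total signal, 0.34 with the series table and 0.29 with hur entries. The split was 83 higher to 0 lower without scaling, 17 to 0 with the percentile over all entries, 26 to 1 with the total signal, 21 to 2 with hur entries, 19 to 11 with quantile normalization and 19 to 16 with the median, beside 17 to 18. It was 18 to 4 with the authors' deposited series table. Falls given here are thus relative to the 56 microRNAs detected on all arrays. The 9 named microRNAs that passed in the same direction under all 7 scalings were all higher in large oocytes: miR-295, miR-223, miR-292-3p, miR-294, miR-652, miR-193, miR-140*, miR-293 and miR-107. None of the scalings moved the median log2 change down, which favours rises. The count of 35 fell to 13 without young small array 1 and to 22 without young small array 2.

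**Figure D3:**
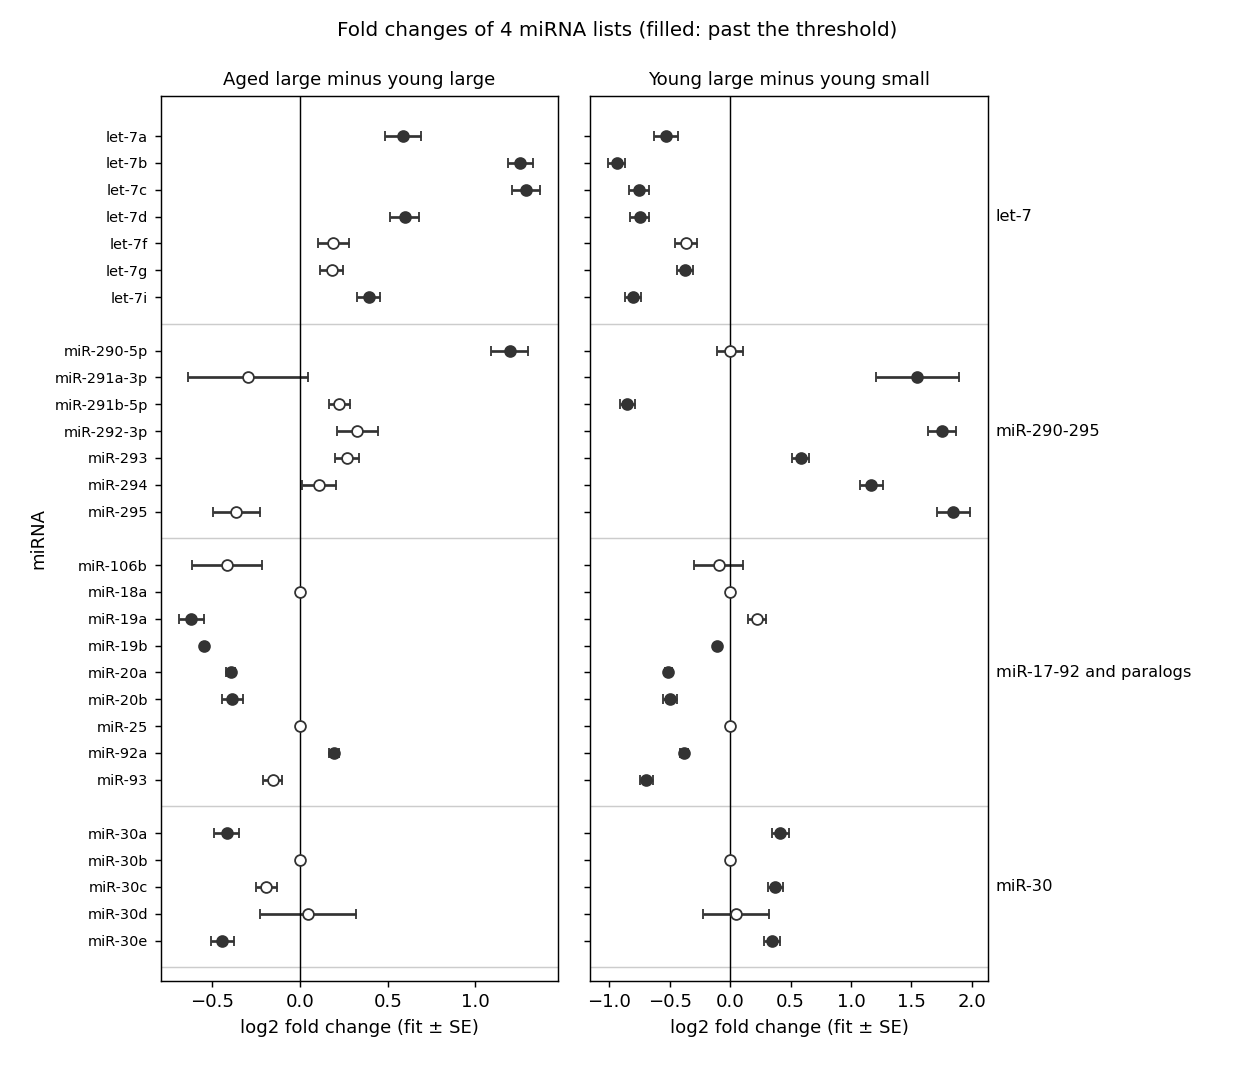
Fitted log2 fold changes with standard errors for the tested members of 4 lists, aged large minus young large oocytes on the left and young large minus young small oocytes on the right; filled points passed the 0.05 threshold. let-7 members lie above 0 on the left and below 0 on the right; without scaling, which is not drawn, the list medians are -0.17 and 0.78. In the miR-290 to miR-295 cluster 5 of 7 members rose on the right.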

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

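All tests of explanations in this part were chosen after the results were seen. Signals outside the main measurement came from 6 control entries that were detected on all 6 arrays and entered no comparison. Their mean raw signals over the 6 arrays were 7864 for hur_1, 32194 for hur_2, 3275 for hur_4, 6558 for hur_6, 612 for miRNABrightCorner30 and 479 for mr_1. By their means the 4 hur entries were brightest in young large oocytes and dimmest in young small ones, for example hur_2 at 45401 ± 2983 and 18023 ± 177 (SD, n = 2), as the microRNAs were. For hur_6 young large and aged large oocytes overlapped, at 8332 ± 903 and 8058 ± 410 (SD, n = 2). mr_1 did not follow that order, with 516 ± 34.8 in young large, 324 ± 17.6 in aged large and 596 ± 3.37 in young small oocytes (SD, n = 2). What these entries hybridise with is not given in the sources used here.

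The viral entry mghv-miR-M1-2 and 5 mouse entries (miR-345-5p, miR-483*, miR-484, miR-702 and miR-715) were at least 2-fold lower on young large array 1 than on array 2 after scaling. Lost spots are argued against: the share of spots kept on array 1 minus array 2 had a median of -0.05 and lay between -0.05 and 0.05. A candidate explanation is signal that does not come from the labelled oocyte RNA: on the aged large arrays, not used to pick the entries, their raw signal exceeded young small by a median of 0.24 log2 units, against 0.72 for 51 other microRNAs detected on all arrays (10 of which were as low). That explanation alone leaves young large array 2 unexplained, where their raw signal was 0.88 to 1.38 log2 units above the other groups' arrays. Extra signal on young large array 2 stays open, since the entries were only 0.21 log2 units further above the other groups' arrays there than the other microRNAs were. No biological explanation was tested for this difference between duplicates.

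After scaling, members of let-7 were lower in young large oocytes than in both other groups. A signal wholly fixed on every array is argued against, as raw let-7 signals were 0.78 log2 units higher in young large than in young small oocytes (median). A fixed part added to oocyte signal stays open. The raw difference was 0.59 for let-7b and 1.17 for the brighter let-7f, and such a part would weigh more on dim members. RNA of cells rich in miR-21, miR-212 or miR-223 is argued against as the whole cause in young small oocytes. The markers miR-21, miR-212 and miR-223 were above the floor on both young large arrays. On the young small arrays miR-212 lay under it on both and miR-223 on 1. Their highest log2 difference from young large oocytes was 0.13 ± 0.11 (SE, miR-21), against a let-7 median of 0.75. For young small oocytes, cells without these markers stay open, because no array shows that the probes of the undetected markers respond. In aged oocytes blood cells stay open. miR-223 rose there by 1.11 ± 0.06 log2 units (SE from these arrays alone), more than the let-7 median of 0.59. The 6 other blood cell markers stayed low (at most 2.08, below), but no array shows that their probes respond. RNA of other ovarian cells cannot be told apart from an effect: miR-212 differed by 0.45 ± 0.50 although miR-21 differed by -0.03 ± 0.09 (SE from these arrays alone). Under the scaling used, the mean let-7 level of young large oocytes lay 0.64 ± 0.08 log2 units (SE, 3 degrees of freedom) under the nearer group. This cannot decide on spread between arrays, because the pattern was picked on these same arrays, which may be technical duplicates. Scaling stays open: without it the list median was -0.17 for ageing and 0.78 for growth. The list call held under 3 of 7 scalings for ageing and 6 of 7 for growth. A deviation common to both young large arrays, age and growth stay open as untested explanations.

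miR-483 and miR-223 were higher in aged large oocytes. For miR-483 scaling is argued against, because the log2 change was 3.03 or more under 7 scalings and passed under each (highest adjusted p = 0.0222). For miR-223 scaling may account for the call but not for the sign, since the lowest change was 0.35 and 3 of 7 scalings kept the call. None of the 6 other blood cell markers was detected on the aged large arrays and their highest scaled signal was 2.08, while miR-223 went from 24.3 ± 0.884 to 52.4 ± 2.72 (SD, n = 2 each). This argues against blood cells as the source of its rise only if those 6 probes respond, which no array here shows. Age stays open as an untested explanation of both, and blood cells stay open for miR-223.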

How the results depend on the processing

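The hur scaling, the runs without the 6 entries or with only microRNAs above the floor, and the crossed block were chosen after the data were seen; causes were not tested unless stated. Normexp correction and a slide or scan date block were not run, since the files used here hold no mean or background signals and no dates. Microarray signal over its error limits the dimmest microRNAs: the median over detected entries was between 7.60 and 8.90 per array. Counts given next are for aged against young large and then for young large against young small oocytes, beside 29 and 35. They were 6 and 17 with the percentile over all entries, 58 and 83 without scaling, 12 and 1 without a filter (577 entries tested), 15 and 23 at a threshold of 0.01, and 5 and 5 with a 2-fold minimum. Growth gave 22 with the series table and 23 with hur scaling. Leaving out 1 array gave 16 to 30 and 13 to 36. The count of lists (1 and 2) became 0 and 0 without scaling or with an estimated correlation, 0 and 1 with the total signal or hur scaling, 2 and 6 without a filter, 5 and 5 with fry, 2 and 1 with only the 4 arrays compared or without the 6 entries. It became 0 for ageing with the median, and for growth 1 with the percentile over all entries or at 0.01 and 4 above the floor. Leaving out 1 array gave 0 to 2 lists in both. Detected microRNAs in young small oocytes became 63 as signals above 3 times their error. Other alternatives, apart from the blocks given next, kept these counts within 1.5 times.

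The labels do not say whether replicate numbers in the titles pair the arrays. Differences between array 1 and array 2 correlated across microRNAs with r = 0.19 for ageing (Spearman's rho -0.18) and -0.18 for growth. Such weak correlations neither show nor exclude a pairing. With the replicate block 16 and 26 microRNAs and 2 and 2 lists passed. With the numbers of young small oocytes crossed, 17 and 26 passed.

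No scaling reversed ageing changes (log2) of miR-150* (-0.18), miR-342-3p (-0.24), miR-709 (-0.16), let-7d (-0.16), let-7i (-0.37), let-7a (-0.17), miR-671-5p (-0.15), miR-720 (-0.31), miR-494 (-0.40), miR-29a (-0.73) and miR-30d (-0.71) and the let-7 list median (-0.17), and total signal that of let-7i (-0.0302). It reversed growth changes of miR-20a (1.023), miR-291b-5p (0.32), let-7b (0.59), miR-709 (0.78), miR-93 (0.84), let-7i (0.73), miR-92a (1.15), miR-26b (1.03), miR-19b (1.43), let-7c (0.78), let-7d (0.78), miR-29b (1.03), miR-877* (0.47), miR-29a (0.95), let-7a (1.004), miR-720 (1.08), miR-16 (1.495), miR-15a (1.41), miR-494 (1.07), miR-155 (1.33), miR-22 (1.49), miR-125b-5p (1.19) and miR-21 (1.40) and the let-7 list median (0.78). These follow from the brighter young large arrays. Growth changes also reversed with the percentile over all entries for miR-92a (0.12), miR-19b (0.39), miR-29b (0.00055) and miR-720 (0.051), with quantile normalization for miR-19b (0.29) and miR-16 (0.28), with total signal for miR-92a (0.039) and miR-19b (0.32), with hur scaling for miR-19b (0.18), and with the series table for miR-19b (0.24), miR-16 (0.30) and miR-15a (0.22). Over single named microRNAs, 1023 ageing and 1023 growth values kept their side of the threshold without a reversed sign. Another 213 and 212 lost the call, 33 and 35 gained one and 46 and 28 moved. The values kept include microRNAs not past the threshold in the main fit, so they do not give the share of calls kept.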

Other observations

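The lists below were chosen beforehand, and the tests of opposing fold changes were chosen after the result was seen. Several lists had few detected members in these oocytes. Of 54 entries of the imprinted Dlk1-Dio3 cluster, 1 was detected, miR-494, with log2 differences of 0.36 ± 0.18 for ageing and -0.47 ± 0.18 for growth (SE), neither past the threshold. Of 25 entries of the Sfmbt2 intron cluster 2 were detected, and of 21 entries of the X-linked testis cluster, which is active in male germ cells, 2 were detected; none passed in either comparison. Of the miR-23, miR-24 and miR-27 clusters 4 members were tested and none passed (miR-24 had -0.02 for ageing and 0.26 for growth; lists by camera, adjusted p = 0.863 and 0.465). The miR-99, miR-100 and miR-125 clusters had 1 detected entry of 7, miR-125b-5p, which lay at or near the floor. Among entries that other RNAs give rise to, miR-720 fell with growth (-0.45 ± 0.10, SE) and had 0.44 ± 0.10 for ageing without passing; 3 of 5 were tested (lists by camera, adjusted p = 0.536 and 0.701). In the growth comparison 0 of 3 tested members of the miR-15 and miR-16 family passed, with a median of -0.04 and a mean of 0.04 (list by camera, adjusted p = 0.817), and 2 of 2 tested miR-29 members fell. In the ageing comparison 0 of 2 tested miR-29 members passed.

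Fold changes of ageing and growth were negatively correlated, and both contain the young large group. Over 53 microRNAs above the floor on all arrays, r was -0.35 (across microRNAs, which are not independent replicates), while groups with no change that share the young large arrays gave a mean r of -0.48 in 10000 simulations. The covariance was -0.0962 against a simulated mean of -0.0112 and a central 95% from -0.0348 to 0.00181, so the spread of the shared arrays alone may not suffice. The simulated groups did not differ, however. Any true difference of young large oocytes from both other groups enters the 2 fold changes with opposite sign. The covariance therefore cannot show that ageing and growth oppose each other. Of 17 microRNAs past the threshold in both comparisons, 7 were higher in aged and lower in large oocytes and 4 the reverse, with 2 higher in both and 4 lower in both; the shared arrays favour opposite calls. With 1 young large array in each comparison, so that none was shared, the covariance was -0.0812 and -0.0787 (simulated central 95% from -0.0252 to 0.0262). A deviation common to both young large arrays is not removed by this split, and neither is a true difference of young large oocytes.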
